A study of Homo sapiens with 6 samples.

How the data were processed

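RNA from uninfected AGS cells and from AGS cells infected with H. pylori strain 60190 was measured after 24 h in 3 experiments that the labels call independent, with 1 array per sample. Per the labels, total RNA was labelled with Cy3 in a one-colour protocol. Groups and experiment numbers were taken from the sample titles and infection labels.

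The authors deposited 1 scanner file per array, made with Agilent Feature Extraction (version 10.5.11 per the submitters' processing notes, 10.5.1.1 per the file headers). Per the file headers these files hold linear spot intensity: a processed signal with background subtracted, and the median pixel brightness of each spot and of its local background. They also hold flags, coded 0 or 1, for spots that are saturated, uneven, outliers or well above background. The array design is annotated on hg18 per the file headers. The authors also deposited a value table of 30102 probes. Set against the scanner files, between 99.7% and 99.9% of its cells lay within 0.001 of the log2 processed signal plus 1 constant per array, between -0.42 and 0.36, so the deposited values are log2 values that the authors shifted by array. Its empty cells were those not well above background. Its column medians were 7.75, 7.71 and 7.81 for uninfected and 7.68, 7.66 and 7.81 for infected replicates 1 to 3. How the constants were chosen is not given in the sources used here. The table served as an alternative.

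Each array held 45015 spots, of which 1639 were controls. Log2 of the processed signal minus the array's 75th percentile over non-control probes was used. That percentile lay between 375 and 700 signal units, and 70.5% to 75.6% of the 41000 distinct probes were well above background. Outlier-flagged spots were left out and spots of 1 probe averaged; saturated spots were kept. Probes well above background on at least 3 of the 6 arrays were kept, 30031 in all. The files used here carry accessions and no gene symbols, so probes were named by matching RefSeq accessions without versions to a gene table of GRCh38.p14. Of the probes, 23680 matched, giving 16422 symbols, and 17320 had no symbol. The build of that table differs from hg18, so no coordinates are given and the table served only for names and gene order. For each gene the probe with the highest mean signal was used, which left 23623 genes, 13044 with a symbol and 10579 under an accession or probe name. Probes of 1 gene can disagree. For genes named by the rule below an opposite sign is stated where they are named, a difference in size only for some. Array brightness relative to background sets how well dim genes are measured. A gene well above background on no array of a group has only a bound there: the bright group's mean over the dim group's mean, with each dim array at the higher of its lowest well-above-background signal and the gene's own. Where only some arrays of a group measured a named gene, their number is given.

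Infected and uninfected samples were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists, fixed before the data were examined, numbered 33, with 711 genes, 693 of them on the array. They were tested with limma's camera (preset correlation 0.01) where at least 5 members were tested, and again with an estimated correlation and with fry. Genes named were fixed by rule before the data were examined: of those passing the threshold with a symbol and one sign in all experiments, up to 12 rises and 12 falls; in each list up to 5 passing members, or else the 2 members with the largest difference; and 10 genes of prior interest. Of the genes this rule names, 2 are not reported here. Figures were drawn with matplotlib 3.10.9.

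The labels name a shared experiment for infected and uninfected arrays of 1 number, and each such pair lay on 1 slide, so experiment and slide are 1 block. Deviations from the group means correlated at 0.33, 0.36 and 0.24 within same-numbered pairs and between -0.37 and 0.10 across numbers. Deviations cancel within each group, so positive values within pairs push those across numbers down, and this contrast is partly built in. By label and slide the numbers pair the samples. The main fit leaves this pairing out, and the fit with the experiment as a block is given as an alternative. On each of the 3 slides the uninfected sample lay at position 1 and the infected at position 2, so position and infection cannot be told apart.

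Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the deposited table, other filters on dim probes, the mean of a gene's probes, every probe, a trended robust variance prior, array weights, the experiment block and leaving out arrays or experiments. Normexp had been planned on the mean signal; the files used here hold no such column, and the median signal was used. Array weights with the block, and list counts without infected replicate 1 or experiment 1, were chosen after seeing the data.

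The fit was tested on simulated data with the means and residual SDs of the 23623 real genes. Over 20 simulations with 200 changed genes each, it called 1.9% of genes changed 2-fold, 49.5% at 4-fold, 78.5% at 8-fold and 90.2% at 16-fold. On average 4.33% of its calls were of unchanged genes. Only the means and residual SDs were taken from the real data. The real arrays are paired by experiment, with deviations correlated at 0.33, 0.36 and 0.24 within pairs. Infected replicate 1 also stands apart. Neither feature was simulated, so the shares called and the false share do not show how the fit fares on the real arrays. With independent genes and no change, camera passed 0.05 lists on average and at most 1. Members of the real lists are correlated, with an estimated correlation as high as 0.78 for cholesterol synthesis. The simulation therefore does not show how camera fares on them.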

Results

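The series measured gene expression in AGS, an established cell line from a human gastric carcinoma, with and without Helicobacter pylori, the bacterium that colonises the stomach. Cells infected with strain 60190 for 24 h were set against uninfected cells in 3 independent experiments, which gives 3 infected and 3 uninfected samples. Each sample was labelled with Cy3 and hybridised alone to 1 Agilent array. Between 70.5% and 75.6% of the probes on an array lay well above background. The number of arrays, 3 per group, limits the precision of every difference below. Differences are infected minus uninfected on the log2 scale, with the standard error of the limma fit, and adjusted p-values are Benjamini-Hochberg values over 23623 genes unless stated.

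The comparison asks how the transcripts of these gastric epithelial cells differ after 24 h with the bacterium. The largest rise was in IL24, a cytokine of the interleukin 10 family, by 5.80 ± 0.38 (adjusted p = 0.0089), which is 55.6-fold. Its uninfected mean of -6.14 lay near the lowest well-above-background signals of those arrays, -6.87, -7.11 and -6.96, so this fold rests on a dim signal. IL20, the neighbour of IL24 in that family, rose by 3.55 ± 0.40. It was not well above background on any uninfected array, so its change is given as at least 3.33-fold. UBD, a ubiquitin-like modifier induced by inflammatory cytokines, rose by 4.94 ± 0.56, and BIRC3, an inhibitor of apoptosis and NF-kB target, rose by 3.43 ± 0.30. VNN1, a pantetheinase, rose by 3.67 ± 0.28, at least 3.29-fold, from uninfected arrays on which it was not well above background. IL4I1, a secreted amino acid oxidase, rose by 2.73 ± 0.30, the collagen gene COL20A1 by 2.52 ± 0.29, CPXM2, of the carboxypeptidase family and well above background on 2 of 3 uninfected arrays, by 2.34 ± 0.28 and the membrane mucin gene MUC4 by 2.32 ± 0.24. Among the falls, FGA and FGG, which encode the alpha and gamma chains of fibrinogen, fell by 3.62 ± 0.34 and 3.06 ± 0.33 on the log2 scale. GJB1, a gap junction gene, fell by 2.16 ± 0.25, at least 2.43-fold, to infected arrays on which it was not well above background, whereas its other probe gave -0.14. With normexp background correction VNN1, IL20 and GJB1 differed by 0.41, 0.42 and -0.11, under the bounds given here, and of these 12 genes only IL24, BIRC3 and FGG passed. The offset of 50 added in that setting narrows differences between dim signals.

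In all, 14 of 23623 genes passed an adjusted p of 0.05, 10 of them higher and 4 lower after infection. Each of the 14 had a fitted difference of at least 2-fold, and its sign was the same in all 3 experiments. Of these, 12 carried a gene symbol. The 2 without one, ENST00000309447 (3.54, at least 3.82-fold) and BX098660 (-2.89, at least 1.79-fold), were chosen for mention after their values were seen. The first was not well above background on any uninfected array, the second on any infected array. The bound for BX098660 lies under 2-fold, so a 2-fold fall is not shown for it. At an unadjusted p under 0.05, 2221 genes differed, where 1181.2 would by chance; of the 9 other splits of the arrays into 3 and 3, 2 gave more, 2268 and 2477, both keeping the arrays of experiment 1 together. The 3 others that part every pair, as infection does, gave 332, 154 and 273 without a block. Both groups of these splits hold infected and uninfected arrays, so an effect of infection would add to their residual spread and lower such counts. With the experiment as a block the real count was 3009, and the other splits were not fitted that way. The experiment number as a block raised the count to 23 genes, 14 higher and 9 lower, of which 12 were among the 14; CPXM2 and GJB1 then missed the threshold, each with an adjusted p of 0.0501. Without 1 array at a time the count was 7 without infected replicate 1, 2 without infected replicate 2, 1 without infected replicate 3, 0 without uninfected replicate 1, 2 without uninfected replicate 2 and 9 without uninfected replicate 3. At an unadjusted p under 0.05 it was 1347 without uninfected replicate 1 and 1057 without uninfected replicate 2, the latter under the 1181.2 expected by chance.

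**Figure D1:**
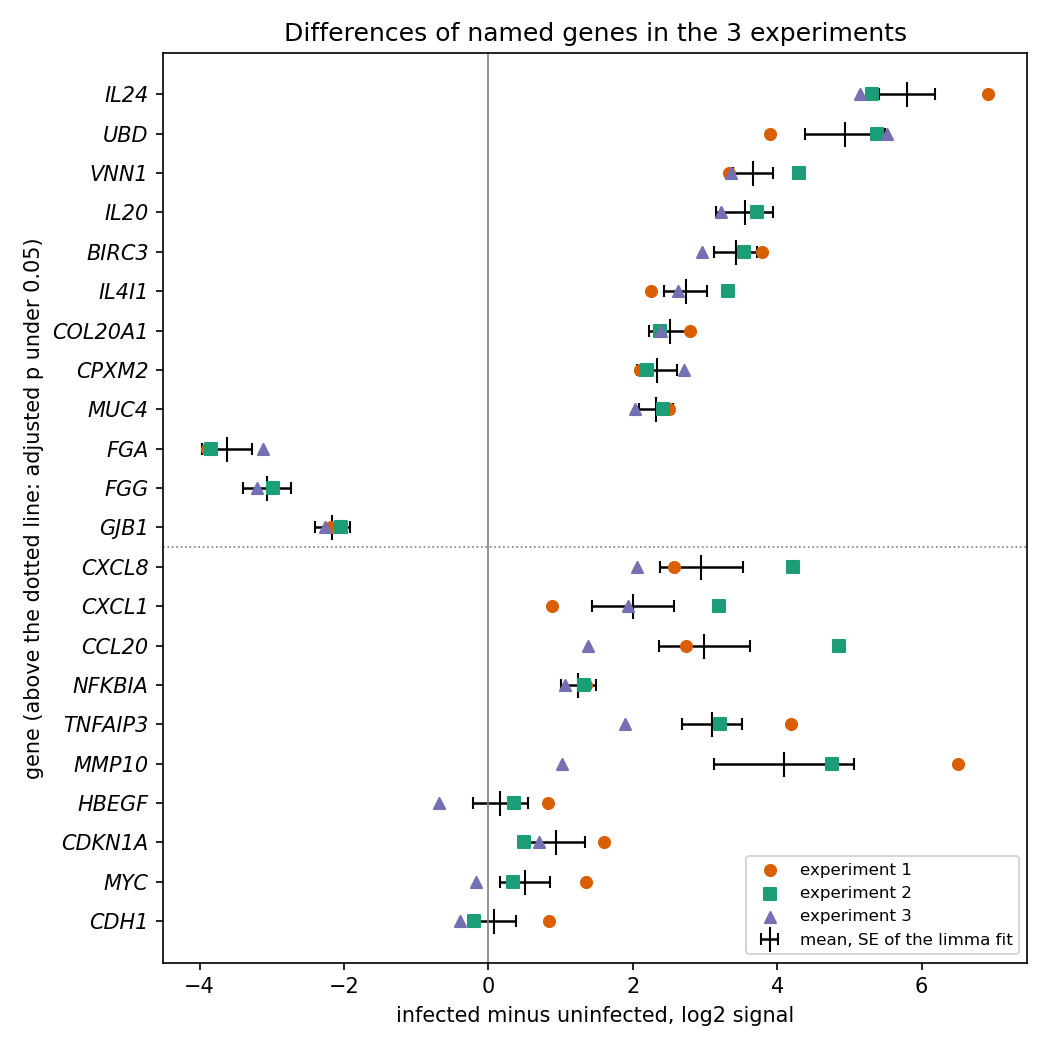
Infected minus uninfected log2 signal (horizontal axis) of the 12 genes with a symbol that passed the threshold and of 10 genes chosen before the data were examined. Coloured symbols are the 3 experiments and black bars the mean with its standard error; IL24 lies between 5.15 and 6.92, whereas MMP10 spans 1.02 to 6.51.

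A wider set of genes moved in one direction in each experiment without passing the adjusted threshold. In 328 genes the difference was over 2-fold the same way in all 3 experiments, 188 higher and 140 lower. Turning the sign of experiment 1, 2 or 3 left 21, 6 and 7 such genes. The sign was shared by all 3 experiments in 37.2% of genes, against 25% by chance.

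Chemokines and cytokines stood higher after infection. Of 23 tested members, 20 had a positive difference, none passed over all genes, and 10 rose when adjusted over the list alone. IL1B, a proinflammatory interleukin, differed by 4.61 ± 0.80 (adjusted p = 0.15), and CSF2, a myeloid growth factor, by 3.87 ± 0.83 (adjusted p = 0.20), at least 9.39-fold from uninfected arrays on which it was not well above background. CXCL8, which attracts neutrophils, differed by 2.95 ± 0.57 (adjusted p = 0.17), CXCL1 by 2.00 ± 0.57 (adjusted p = 0.32) and CCL20 by 2.99 ± 0.63 (adjusted p = 0.20), at least 4.49-fold. With normexp CSF2 and CCL20 differed by 0.93 and 0.62, under these bounds. The median of the list was 0.98, with 0.88, 1.04 and 0.59 in experiments 1, 2 and 3; it was as low as 0.38 in another setting, normexp. By limma's camera with a preset correlation the adjusted p was 2.9e-08, and the adjusted p was 0.18 with an estimated correlation. By fry, which tests whether the members move on balance one way, the adjusted p was 0.022.

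Targets and feedback regulators of NF-kB, the transcription factor of inflammatory signalling, also stood higher. Of 24 tested members 23 had a positive difference, BIRC3 passed over all genes, and 9 rose when adjusted over the list alone. TNFAIP3, which limits NF-kB signalling, differed by 3.10 ± 0.42 (adjusted p = 0.079), and its inhibitor NFKBIA by 1.24 ± 0.24 (adjusted p = 0.17). TNFRSF9, chosen after its value was seen, is 1 of these 9 and was well above background on 2 of 3 uninfected arrays; over all genes it passed only with the experiment as a block (3.57, adjusted p = 0.017). The list's median was 0.60, with 1.01, 0.57 and 0.39 in the 3 experiments. The adjusted p was 2.7e-13 by camera, 0.18 with an estimated correlation and 0.022 by fry.

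Among 32 lists with at least 5 tested members, camera put 14 past an adjusted p of 0.05. With an estimated correlation no list passed, and by fry only chemokines and NF-kB passed. The lists below therefore rest on the preset correlation, and for each the adjusted p with an estimated correlation follows it. Infected replicate 1 stood apart from the other 5 arrays, as described at the end, so medians are given per experiment.

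Matrix proteases and their inhibitors had a median of 0.35, with 0.63, 0.14 and 0.44 in the 3 experiments and 0.20 with normexp, and 6 of 26 tested members rose when adjusted over the list alone (adjusted p = 3.5e-05 by camera, adjusted p = 0.59 with an estimated correlation). SERPINB2, a serine protease inhibitor, differed by 4.33 ± 0.70 (adjusted p = 0.13), at least 5.98-fold though 0.70 with normexp, and MMP10 by 4.10 ± 0.97 (adjusted p = 0.24). Without infected replicate 1 the median was 0.10 and 5 members rose by that count, and without both arrays of experiment 1, 3 did. Immediate-early transcription factors had a median of 0.77, with 1.35, 0.68 and 0.25 in the 3 experiments and 0.51 without infected replicate 1. No member passed over all genes or over the list alone. With the experiment as a block 4 members rose over the list alone. ATF3 differed by 1.60 ± 0.52, MAFF by 1.47 ± 0.54 and MYC by 0.51 ± 0.35. Its adjusted p was 2.4e-06 by camera and the adjusted p was 0.59 with an estimated correlation.

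The oxidative stress and polyamine list had a median of 0.70, with 1.19, 0.74 and 0.38 in the 3 experiments, and 5 of 20 members rose when adjusted over the list alone. Without infected replicate 1 that count was 1 and without experiment 1 it was 0. AKR1C1 and AKR1C3, aldo-keto reductases, differed by 4.19 ± 1.05 and 2.79 ± 0.74 (adjusted p = 0.26 and 0.28), AKR1C1 being well above background on 2 of 3 uninfected arrays. The lowest difference among the 3 probes of AKR1C1 was 1.78. The list's adjusted p was 3.3e-08 by camera and the adjusted p was 0.59 with an estimated correlation. Antimicrobial and mucosal defence genes went both ways: of 15 tested members, 4 rose and 1 fell when adjusted over the list alone. LYZ, lysozyme, differed by -2.12 ± 0.26 (adjusted p = 0.061) and REG3A, a secreted lectin, by 1.49 ± 0.44. The median was 0.23, with 0.32, 0.94 and 0.66 in the 3 experiments, and the adjusted p was 0.018 by camera, 0.59 with an estimated correlation, and 0.19 by camera without infected replicate 2. With normexp background correction the camera adjusted p was 0.070, and without infected replicate 1 the median was 0.67.

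Of 14 tested H. pylori receptor and glycan enzyme genes, 5 rose when adjusted over the list alone, led by CEACAM5 (1.93 ± 0.31, adjusted p = 0.13) and CD55 (1.47 ± 0.46, adjusted p = 0.38). The list's median was 0.35, with 0.94, 0.23 and 0.03 in the 3 experiments (adjusted p = 0.0089 by camera, adjusted p = 0.59 with an estimated correlation); without infected replicate 1 the median was 0.02 and the camera call was lost, with an adjusted p of 0.24, and without experiment 1 only 2 members rose over the list alone. Of 9 tested leukocyte markers all had a positive mean difference, CD68 with 2.40 ± 0.63 and ITGAX with 0.82 ± 0.50, and 1, CD68, rose when adjusted over the list alone. Only CD68 and ITGAM, which was chosen for mention after its value was seen, were positive in all 3 experiments. Their median was 0.29, with 0.40, -0.14 and 0.72 in the 3 experiments (adjusted p = 0.021 by camera, adjusted p = 0.63 with an estimated correlation), and the camera adjusted p was 0.24 without infected replicate 1, 0.18 without uninfected replicate 3 and 0.055 with normexp. Over single left-out arrays the median lay between 0.13 and 0.66.

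Interferon response genes stood lower. Of 28 tested members 24 had a negative difference and 6 fell when adjusted over the list alone, among them IFI44L (-2.53 ± 0.65, well above background on 2 of 3 infected arrays) and IFI44 (-2.02 ± 0.54). The median was -0.73, with -1.07, -1.04 and -0.09 in the 3 experiments, and -0.47 without uninfected replicate 2. The adjusted p was 3.3e-08 by camera and the adjusted p was 0.59 with an estimated correlation. Without infected replicate 1, and without experiment 1, no member passed over the list alone. Targets of Wnt signalling had a median of -0.60, with -0.63, -0.67 and -0.29 in the 3 experiments, and none of 15 members passed over the list alone, against 3 without infected replicate 1. SP5 differed by -0.92 ± 0.29, with 1 of its 3 probes of the opposite sign, and DKK4, well above background on 1 infected and 2 uninfected arrays, by -0.93 ± 0.59. The adjusted p was 6.7e-05 by camera and the adjusted p was 0.42 with an estimated correlation.

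For 4 further lists past the camera threshold most of the difference lay in experiment 1, and no member passed over the list alone. Cholesterol synthesis genes had a median of 1.11, made of 3.03 in experiment 1 against 0.24 and 0.25 in experiments 2 and 3; INSIG1, a regulator of sterol sensing, differed by 2.42 ± 1.16 and MSMO1, an enzyme of the pathway, by 2.08 ± 0.83. G1/S and DNA replication genes had -0.64, made of -1.65, -0.35 and 0.02, with CDC45 at -1.35 ± 0.72 and GINS2 at -1.23 ± 0.60. Homologous recombination and Fanconi genes had -0.51, made of -1.40, -0.03 and -0.07, with FANCC at -1.09 ± 0.41 and FANCA at -1.07 ± 0.45. Hypoxia and glycolysis genes had 0.50, made of 1.06, 0.23 and 0.31, with ALDOC at 2.16 ± 0.95 and NDRG1 at 2.04 ± 0.72. With an estimated correlation their adjusted p-values were 0.63, 0.63, 0.64 and 0.63. Without infected replicate 1 the camera adjusted p was 0.11 for replication and 0.54 for recombination, with medians of -0.16 and -0.05. Without both arrays of experiment 1 it was 0.023 for replication and 0.41 for recombination, with medians of -0.14 and -0.07. The hypoxia median without infected replicate 1 was 0.18, with a camera adjusted p of 0.038.

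**Figure D2:**
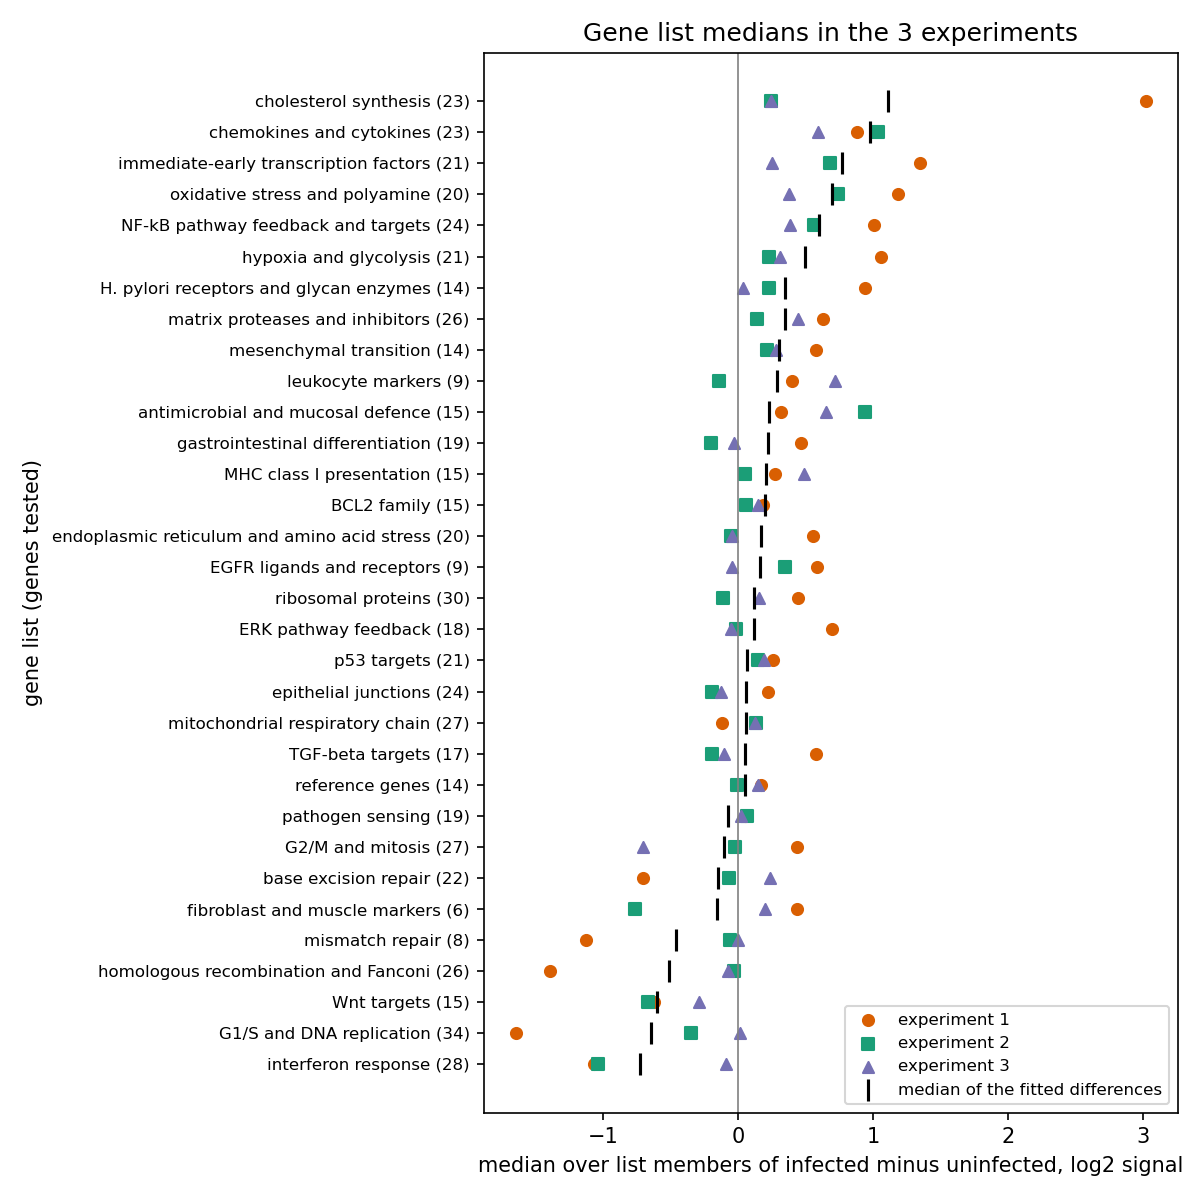
Median infected minus uninfected log2 signal of the members of each of 32 gene lists (horizontal axis), with the number of tested genes in parentheses. Coloured symbols are the 3 experiments and black bars the median of the fitted differences; cholesterol synthesis lies at 3.03 in experiment 1 and at 0.24 and 0.25 in the others.

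In the gastrointestinal differentiation list, which did not pass as a whole (camera adjusted p = 0.76), MUC4 passed over all genes and 5 of 19 members passed over the list alone, 2 higher and 3 lower. The epithelial junction list (camera adjusted p = 0.82) held 1 member that fell over the list alone, CLDN2, a claudin of leaky epithelia, with -2.70 ± 0.37 (adjusted p = 0.079). TJP1 differed by 0.99 ± 0.32, with 0.07 on its other probe, and CDH1, the epithelial cadherin, by 0.08 ± 0.30. In the pathogen sensing list TLR6, well above background on 2 of 3 uninfected arrays, differed by 1.38 ± 0.27 and TLR4, a lipopolysaccharide receptor, by -1.08 ± 0.23; these 2 passed over the list alone, neither did without experiment 1, and the list's median was -0.07. Of the TGF-beta targets, 2 passed over the list alone, 1 higher and 1 lower, and 5 did with the experiment as a block; INHBA, well above background on 1 of 3 uninfected arrays, differed by 2.82 ± 0.72 and ANKRD1 by 1.90 ± 0.90. In ERK pathway feedback DUSP10, a MAP kinase phosphatase, rose over the list alone by 2.19 ± 0.47, joined by 1 more member with the experiment as a block, and DUSP4 differed by 1.54 ± 0.48. Of the EGFR ligands and receptors none passed; EGFR differed by 1.47 ± 0.59, ERBB4, well above background on 1 infected and 2 uninfected arrays, by -1.30 ± 0.83 and HBEGF by 0.17 ± 0.39.

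No member passed over the list alone in the remaining cell-state lists, and none of these lists passed camera in the main setting. With normexp base excision repair and mismatch repair passed (camera adjusted p = 0.0043 and 0.0080), and further settings passed some of these lists, as given at the end. For p53 targets CDKN1A, the cell cycle inhibitor, differed by 0.93 ± 0.41 and PLK3 by 0.76 ± 0.38. In the mesenchymal transition list SNAI1 differed by 1.53 ± 0.61. Mitosis was represented by MKI67 (-1.17 ± 0.35) and PTTG1 (0.54 ± 0.47), base excision repair by UNG (-1.08 ± 0.54) and NEIL3 (-1.02 ± 0.70), and mismatch repair by MLH3 (-0.63 ± 0.28). In the BCL2 family BCL2, well above background on 2 of 3 infected arrays, differed by -0.82 ± 0.63 and HRK by 0.62 ± 0.55, and in the endoplasmic reticulum and amino acid stress list PHGDH, well above background on 2 infected and 1 uninfected arrays, by 1.17 ± 0.63 and PPP1R15A by 1.16 ± 0.45. MHC class I presentation held NLRC5 (0.61 ± 0.34, with 2 of 3 probes of the opposite sign) and TAPBP (0.47 ± 0.28). Respiratory chain genes NDUFB5 and CYCS differed by 0.61 ± 0.50 and 0.40 ± 0.29, with 2 of the 3 CYCS probes of the opposite sign. The medians of the ribosomal protein and reference gene lists were 0.12 and 0.05, and -0.05 and -0.06 after quantile normalization; RPS15, RPL22, GAPDH and PGK1 differed by 0.36 ± 0.27, -0.29 ± 0.32, 0.67 ± 0.41 and 0.65 ± 0.42. Markers of other cell types outside leukocytes gave 1 passing member over its list alone, PDGFRA among fibroblast and muscle markers (-1.22 ± 0.29), where DCN, well above background on 2 arrays of each group, differed by -0.37 ± 0.75; only 4 endothelial markers were tested, with CDH5, well above background on 1 of 3 infected arrays, at -1.48 ± 0.78 and VWF at 0.80 ± 0.67.

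The array of infected replicate 1 differed from the others. Over all tested genes it correlated with the other 5 arrays at 0.94 to 0.96, whereas those correlated with one another at 0.97 to 0.99. The first principal component held 54.2% of the variance and set this array at 0.88, against -0.32 to 0.02 for the rest. The SD of the log2 differences was 1.03 in experiment 1 and 0.60 and 0.54 in experiments 2 and 3, and 6109, 1717 and 1487 genes differed over 2-fold in them. No pair of arrays was identical. The 75th percentile of infected replicate 1 was the lowest, 375 signal units against 428 to 700 on the others. The slope of the line fitted to its spike-in controls was also the lowest, 0.94 against 0.97 to 0.98. Its share of probes well above background, 70.8%, lay within the range of the others, 70.5% to 75.6%. Whether signal level or slope accounts for its standing apart was not tested.

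**Figure D3:**
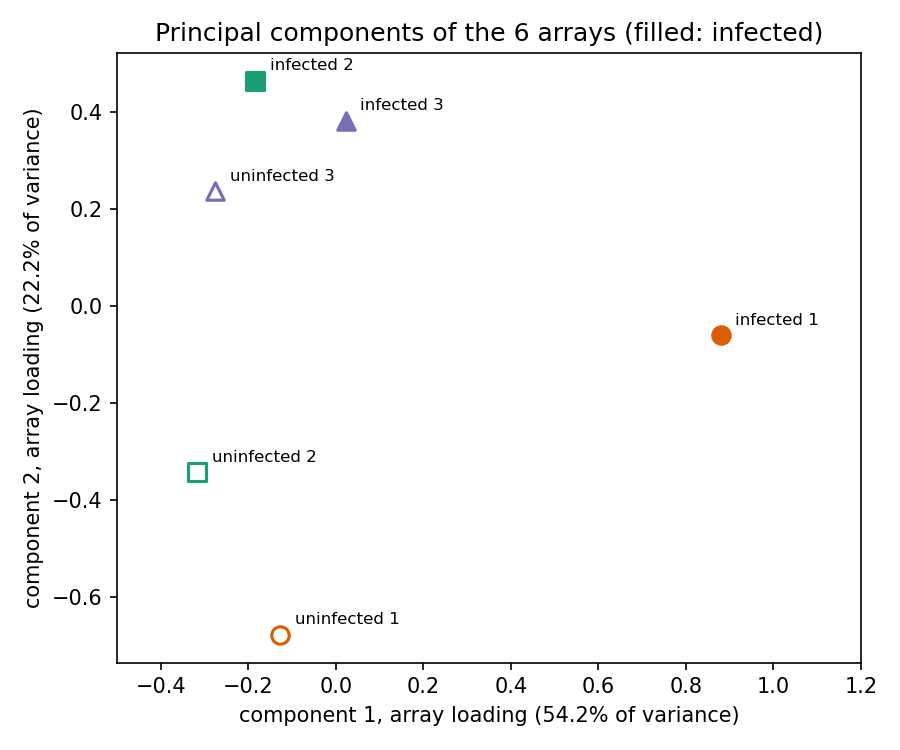
Loadings of the 6 arrays on principal components 1 and 2 (no unit), holding 54.2% and 22.2% of the variance. Filled symbols are infected and open symbols uninfected arrays, with 1 symbol shape per experiment; infected replicate 1 lies at 0.88 on component 1 and all others at 0.02 or below.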

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

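Array weights with the block were chosen after seeing the data; the other settings before. The count of 14 genes (10 higher, 4 lower) depended on the processing. It was 9 with normexp (6 higher), of which 3 were among the 14, 8 with quantile normalization (5 higher), 5 with the deposited table or with no filter (3 higher, 2 lower), 8 with probes well above background on all 6 arrays (6 higher, 2 lower) and 6 with a trended robust prior (4 higher, 2 lower). The same counts hold for genes with a fitted difference of at least 2-fold. The replicate block gave 23 genes, all at least 2-fold, 9 of them lower, and the same 14 lists passed camera; over the list alone it passed 11 chemokines, 7 interferon response and 6 oxidative stress genes, and other calls it changed are given with the results. Array weights gave 10294 genes (4917 higher, 5377 lower, 2311 at least 2-fold) and 8 lists, without cholesterol synthesis (adjusted p 0.13), H. pylori receptors (0.22), antimicrobial (0.12), leukocyte (0.13), replication (0.66) and recombination (0.60), with weights of 7.86 and 6.44 on uninfected replicate 2 and infected replicate 3 and 0.13 to 0.60 on the others, so that fit rests on 2 arrays. With the block added it gave 182 genes (101 higher, 81 lower, 182 at least 2-fold). Leaving out arrays or experiments gave 0 to 9 genes, 0 to 7 higher and 0 to 2 lower, from fewer samples. Lists past the threshold were 0 with an estimated correlation and 2 by fry. The cause of the other changes was not tested. With normexp the dim genes VNN1, IL20, CSF2, CCL20, SERPINB2 and GJB1 differed by 0.41, 0.42, 0.93, 0.62, 0.70 and -0.11, each under the bound given in the report. The offset of 50 narrows differences between dim signals, and how far this accounts for these values was not tested. The chemokine list passed camera in every setting except the estimated correlation, but its median of 0.98 was 0.38 with normexp, 0.57 with the deposited table, 0.62 with no filter and 0.52 with array weights. With normexp the medians of the matrix protease, leukocyte and recombination lists were 0.20, 0.19 and -0.24. Some lists passed camera only elsewhere: with no filter base excision repair (adjusted p 0.044), mismatch repair (0.038) and mesenchymal transition (0.044), and with the mean of probes mismatch repair, mesenchymal transition and ERK feedback (0.047 each). Mitosis passed with array weights and the block (0.0024) and, in both directions, with arrays left out: lower without uninfected replicate 1 (0.0012) and higher without uninfected replicate 3 (0.018). With arrays or experiments left out MHC class I, endoplasmic reticulum stress, ribosomal proteins, ERK feedback, base excision repair, mismatch repair and mesenchymal transition also passed, at lowest 0.038, 0.023, 0.0061, 0.012, 0.0030, 0.014 and 0.023.

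Some named genes that passed no test in the main setting changed sign in others. With normexp BCL2 was 0.092, CDH5 0.022 and DKK4 0.079. With array weights BCL2 was 0.51, CDH1 -0.40 (adjusted p 0.035, past the threshold in the turned direction), MYC -0.092 and VWF -0.026, and with the block added CDH1 was -0.17 and HBEGF -0.090. CYCS was -0.23 as the mean of its probes. Over left-out replicates BCL2 ranged from -1.46 to 0.14, CDH1 from -0.29 to 0.32, DCN from -1.04 to 0.49, HBEGF from -0.20 to 0.59, NDUFB5 from -0.18 to 1.28 and VWF from -0.068 to 1.32.

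The direction of the camera test turned for lists as follows, with their medians. With normexp they were TGF-beta targets 0.040, gastrointestinal differentiation 0.18 and respiratory chain -0.038. With quantile normalization they were respiratory chain -0.043, reference genes -0.064 and ribosomal proteins -0.047. With no filter pathogen sensing was -0.064, and with the mean of probes epithelial junctions were 0.11. With array weights they were mitosis 0.21, base excision repair 0.083, gastrointestinal differentiation -0.029, recombination 0.13 and pathogen sensing 0.087. With the block added they were EGFR ligands 0.058, TGF-beta targets -0.079 and gastrointestinal differentiation -0.0019. Over left-out replicates medians ranged from -0.16 to 0.59 for EGFR ligands, -0.37 to 0.28 for mitosis, -0.029 to 0.42 for MHC class I, -0.22 to 0.38 for TGF-beta targets, -0.29 to -0.0035 for base excision repair, -0.060 to 0.36 for endoplasmic reticulum stress, -0.14 to 0.16 for junctions, -0.11 to 0.38 for gastrointestinal differentiation, -0.029 to 0.12 for the respiratory chain, -0.16 to -0.014 for pathogen sensing and -0.088 to 0.35 for ribosomal proteins. Of these lists only recombination had passed camera over all arrays.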

Other observations

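Gene families in this paragraph and the next, and the metallothionein and cholesterol tests, were chosen after the result was seen. All 9 tested metallothioneins, small proteins that bind zinc and other metals, had a positive difference, from 1.12 to 3.61, and 8 of them in all 3 experiments; MT1F was -0.01 in experiment 2. MT2A differed by 3.32 and MT1X by 2.97, and none passed over all 23623 genes (MT2A adjusted p = 0.17). SLC30A1, a zinc exporter, differed by 1.33 ± 0.39 (adjusted p = 0.34), and SLC39A10, a zinc importer, by -1.86 ± 0.35 (adjusted p = 0.17). All 8 tested pregnancy-specific glycoprotein genes had negative differences in all 3 experiments, from -2.22 to -3.29, with a median of -4.70 in experiment 2 and -1.94 and -1.95 in the others. None of the 8 passed over all genes. Their sequences are near-identical, so single members cannot be separated with certainty.

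Of the interleukin 10 family, IL10, IL19, IL20 and IL24, which neighbour each other in that order in the GRCh38.p14 gene table, differed by 1.55, 2.04, 3.55 and 5.80, and IL26 by 0.07; IL19 and IL26 were well above background on 1 and 2 of 3 uninfected arrays. Of the fibrinogen genes, FGA differed by -3.62 and FGG by -3.06, while FGB differed by -0.79 and was 0.54 in experiment 2. F5, coagulation factor V, differed by -1.64 ± 0.26, with -1.75, -1.58 and -1.58 in the 3 experiments. The fibrinogen genes and F5 belong to a family of 20 liver-type secreted proteins. Of its 16 tested members 6 were lower and 1 higher in all 3 experiments, with differences from -3.62 to 0.66 and a median of -0.68. CYP1A1, a target of the aryl hydrocarbon receptor, differed by 4.72 ± 0.86 (adjusted p = 0.16) and TIPARP, another target, by 1.89 ± 0.41 (adjusted p = 0.20). CYP1A2 differed by -0.09 on its brighter probe and 3.56 on the other. The other tested genes chosen with them, UGT1A6, NQO1, ALDH3A1 and NFE2L2, differed by 0.97, 0.68, 0.31 and 0.30. Apart from IL20, IL24, FGA and FGG, no gene of this paragraph passed over all genes.

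The metallothionein rise may follow free zinc or another metal. In all 3 experiments SLC30A1, which zinc raises, was higher and SLC39A10, which zinc lowers, was lower. The rise was not confined to infected replicate 1, since the family's median was at least 1.78 in experiments 2 and 3. This value and the transporters were both taken up after the result was seen, so neither is a test fixed in advance. Cross-hybridisation between copies stays open: 2 of the 9 members, MT1F and MT1M, left the family's profile over the experiments by over 1, while the rest followed it, as a single rising copy read by several probes would also give. The transporters do not bear on that point. Position on the slide was not separable from infection.

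Several accounts of why infected replicate 1 stands apart were tested. Dim probes on that array are argued against as the whole cause. Bright genes should then be spared, with a ratio of its SD of differences to that between the other infected arrays of no more than 1.2, as set before the result was seen. The smaller of its 2 SDs, 1 per other infected array, was used. Among the brightest 25% of genes the ratio was 1.51, with a bootstrap 95% interval of 1.46 to 1.57, against 1.63 among the dimmest 25% and 1.69 over all genes. That interval resamples genes as if independent and does not measure the spread between arrays. The interval also spans 1.5, the value set beforehand against this account. The rule for weighing the ratio against these 2 bounds was changed after the result was seen, so the exclusion was not fixed in advance. A part played by dim probes stays open, as do the accounts that follow. A stronger form of a shared response was not settled. Of the 1440 genes at least 4-fold in experiment 1, 32.2% moved by at least 0.5 the same way in both others. That lies between the shares set beforehand for and against this account. By the same measure experiment 2 gave 63.4% of 309 genes and experiment 3 gave 56.8% of 155. A second measure used the 478 genes at least 2-fold one way in experiments 2 and 3. Their median ratio of the experiment 1 difference to the mean of the others was 1.01, where over 1.5 had been set beforehand for this account. A separate sterol and growth state could not be tested as planned: leaving out 161 list genes lowered the share of the first component by 0.538% of itself, and no more than 1.08% was possible, so the bound of 5% set beforehand could not have been missed. The cholesterol list's median was 0.30 without infected replicate 1, with a camera adjusted p of 0.00038, and 0.25 without experiment 1, with 0.022; it passed in both, at a lower median, and did not pass with array weights (median 0.36, adjusted p 0.13).

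Adjacent genes with unlike names had correlated differences (r = 0.0621 across 12159 pairs, Spearman's rho 0.0469), and none of 10000 shuffled orders exceeded 0.0325 (p = 1e-04, the smallest these can give). Genes are not independent replicates. The value is small, and may reflect shared regulation or shared sequence, which were not separated.

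Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave 14 genes, 10 higher and 4 lower, all with a fitted difference of at least 2-fold, and the highest of the others gave 0. Each other split puts infected and uninfected arrays in both groups. An effect of infection would then add to its residual spread and lower its count, so 14 against 0 is partly set by the design. For lists by camera 4 of the 10 splits gave as many as the real 14, and the highest other gave 17. The splits with a camera p as small, the real one included, were 7 for recombination, 5 for cholesterol synthesis and 4 for replication and leukocyte markers. They were 3 for immediate-early factors, oxidative stress and hypoxia, and 2 for interferon response. For chemokines, NF-kB, matrix proteases, antimicrobial defence, H. pylori receptors and Wnt targets it was 1, the real split. By fry the real split passed 2 lists and each other split 0, where the same added spread would lower the count. With 10 splits a share under 0.05 cannot be reached. The splits that part all 3 pairs, as the real one does, number 4.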
